A study of Mus musculus with 16 samples.

How the data were processed

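Undifferentiated spermatogonia, the mitotic germ cells of the testis that include the stem cells of spermatogenesis, were collected by fluorescence-activated cell sorting from adult mice 10 days after busulfan. Busulfan is an alkylating drug that kills dividing germ cells. It was injected at 10 mg/kg, and from day 3 the mice received daily injections for 7 days of PD0325901 at 2.5 mg/kg, an inhibitor of the kinases MEK1 and MEK2 that activate ERK, or of vehicle with 10% DMSO, per the labels' protocols. Wild-type mice and mice with a germline knockout of Spry4 were each given inhibitor or vehicle. Spry4 encodes a feedback inhibitor of receptor tyrosine kinase signalling to ERK. The column names in the labels carry Spry4ff for the libraries titled wild type and GCRT_Spry4KO for the knockout, which is titled Spry4 G-KO. GCRT stands only in the knockout names, so any effect of what it names cannot be told apart from the loss of Spry4. The 4 groups held 4 polyA RNA libraries each, prepared with a stranded mRNA kit, per the labels' protocols. The surface markers used in the sort and the part of Spry4 removed in the knockout are not given in the sources used here.

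The deposited values are FPKM, sequenced fragments per kilobase of gene scaled to library size, which the authors computed for each library, per the labels. FastQC, STAR 2.7.10a and edgeR 4.0.14 are named per the submitters' processing notes, with no role stated. The same notes name the builds mm10 and GRCm39, without saying which was used for these values. The read counter, the gene lengths, any scaling between libraries and any filter on genes are not given in the sources used here. The table lists 16383 genes by symbol, and each library's column was matched to its sample by the column name in the labels. Of these symbols, 15791 (96.4%) matched the GENCODE M21 annotation of the mouse genome build GRCm38, which was used for gene identifiers and positions. The genes stand in the order of their identifiers for 99.9% of neighbouring pairs, and 1868 of 21951 protein-coding genes of that annotation have identifiers above the last one listed, so a gene missing from the table was not analysed here and is not taken as unexpressed.

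The library size behind the FPKM values was estimated from the low values. A gene's FPKM multiplied by its exon length and by the right library size must be a whole number of reads. The estimated library sizes, which are the divisors of the FPKM values, ran from 23838600 to 83908300. With them, 92.9% to 93.9% of the values under 100 reads lay within 0.1 of a whole number. Reads in the listed genes came to 24282400 to 73445900 per library, or 86.7% to 113% of that divisor. Whether the divisors hold a scaling factor as well as depth could not be told from the values. A value of 1 FPKM thus stands for 23.8 reads per kilobase of exon in the shallowest library and 83.9 in the deepest.

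Each comparison was made with limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5). The 12907 genes with an FPKM of at least 1 in at least 4 libraries were tested, and 3476 were left out. A model with 1 mean per group was fitted to all 16 libraries, and variances were moderated with a trend on the mean level. P-values were adjusted by the Benjamini-Hochberg method over the genes tested within a comparison, with 0.05 as the threshold. All log2 differences are on the log2(FPKM + 0.5) scale, which understates the change of genes near or below 1 FPKM. The 6 comparisons were knockout against wild type under vehicle and under inhibitor, inhibitor against vehicle in each genotype, the interaction of genotype and inhibitor, and inhibitor-treated knockout against vehicle-treated wild type. Differences of a single value between groups of 4 were also tested with a two-sided exact permutation test, whose smallest possible p is 0.0286. The labels do not say that the replicates of a group came from separate animals, so the p-values measure the spread between these libraries.

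The model, the filter, the 30 gene lists and the rule for the genes named were fixed before the data were examined. The rule named Spry4, Etv5, Dusp6, Gfra1, Nanos2, Neurog3, Kit, Zbtb16, Mki67 and Cdkn1a in every comparison, with the changed genes of largest effect in each, or, where no gene passed the threshold, the 5 genes with the smallest p whose libraries did not overlap between the groups (for the interaction, without that condition). Predicted genes and pseudogenes were left out of those 5. Other genes named as examples of a list or cell type, Etv4 included, fell outside this rule. They were picked after their values were seen, so they illustrate a list and do not test it. The lists covered germ cell stages (stem cell, progenitor, pan-undifferentiated, differentiating, meiotic, spermatid), signalling (ERK pathway output, immediate early, GDNF-responsive, p53 targets, interferon response, retinoic acid response), cell state (homologous recombination and crosslink repair, mitotic cell cycle, DNA replication, quiescence and FOXO targets, apoptosis regulators, ribosome biogenesis, amino acid stress and ATF4 targets, glycolysis, oxidative phosphorylation, cholesterol synthesis, heat shock and dissociation stress, mitochondrially encoded) and other cells (Sertoli, Leydig, peritubular myoid, macrophage and leukocyte, endothelial, erythrocyte). The 27 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. The same lists were tested with a correlation estimated from the residuals, with limma's fry, and, as a test chosen after seeing the data, with an exact permutation of the list mean per library. Within each list, members were also counted past the threshold when adjusted over the list alone.

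The limma step was tested on simulated data in which 200 of the 12907 genes were changed in 10 draws per comparison, with the real residuals dealt to the groups at random. For knockout against wild type under vehicle it recovered 74.7% of genes changed 2-fold and 94.3% of genes changed 4-fold, with 1 false call per draw on average. For the same comparison under inhibitor the shares were 74.5% and 93.5%, with 5.1 false calls. For inhibitor against vehicle they were 73.4% and 93.2% in wild type, with 8.3 false calls, and 74.8% and 92.8% in the knockout, with 0.4. These shares hold only where many genes change together, because the adjusted threshold is stricter when few genes have a small p. In the real vehicle comparison Spry4 itself, at a log2 difference of -1.01, had a limma adjusted p = 0.9998. A count of 0 genes therefore does not rule out single 2-fold changes.

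Alternatives were other pseudocounts (0.1 and 1), other filters, 3 other scalings between libraries, fits of the compared groups alone, robust moderation, library weights, the replicate number as a block, the order of library numbers as a term, and, for genes, each library left out in turn. Other alternatives were chosen after seeing the data. They were terms for the content of peritubular myoid and spermatid transcripts, a fit without the 2 libraries farthest apart on the first principal component, limma's voom on reads recovered from the FPKM values, each library left out in turn for the lists, a fit without WT_vehicle 4 and WT_PD 4, and the correlation of each list mean with the peritubular list mean. The labels number the libraries from 440 to 455. In each group, replicates 1 and 2 have the lower 8 numbers (440 to 447) and replicates 3 and 4 the higher 8 (448 to 455), which were treated as possible batches, and 1521 genes passed the threshold between these sets with group in the model. The columns of WT_vehicle 4 and WT_PD 4 (455 and 454) have up to 9 decimals and the other 14 have 4, for a reason not given in the sources used here. No 2 libraries held identical values. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for depth, correlations and figures.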

Results

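Transcript levels were measured by mRNA sequencing in undifferentiated spermatogonia sorted from adult mice 10 days after busulfan. The 16 libraries fell into 4 groups of 4: wild type with vehicle, wild type with the MEK inhibitor PD0325901, Spry4 germline knockout with vehicle, and Spry4 germline knockout with PD0325901. The divisors of the FPKM values, estimated as library sizes and not taken as depth alone, ranged from 23838600 to 83908300. Each library had between 12257 and 12805 genes at 1 FPKM or more. The series title places SPRY4 and ERK in the recovery of spermatogenesis after damage to germline stem cells. The comparisons therefore ask what loss of Spry4, inhibition of MEK, and both together do to the transcripts of the surviving undifferentiated cells. Single libraries are named below by group and replicate, as WT_vehicle 2 or KO_PD 3.

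Spry4 (ENSMUSG00000024427, GRCm38 chromosome 18, 38586247 to 38601415, minus strand) was lower in the knockout under both treatments but did not disappear. Its level was 22.1 ± 1.66 FPKM (SD, n = 4) in wild type with vehicle and 11.0 ± 3.13 FPKM in knockout with vehicle. With PD0325901 it was 21.5 ± 4.89 FPKM in wild type and 12.9 ± 4.71 FPKM in the knockout. Under vehicle all 4 knockout libraries lay below all 4 wild-type libraries, at 49.7% of the wild-type level (log2 difference -1.01, exact permutation p = 0.0286, the smallest possible, adjusted over 2 tests 0.0571). Under inhibitor 1 knockout library overlapped the wild type, and the level was 59.3% of wild type (log2 difference -0.75, exact permutation p = 0.0571). Without replicate 4 of the inhibitor-treated knockout, the library that overlapped (19.3 FPKM), this difference was -0.96, with exact permutation p = 0.0286. That p is the smallest possible for the libraries left and follows from removing the overlap, so it adds no support. The range over all single libraries left out is given below. The inhibitor itself left Spry4 within the spread between replicates, with log2 differences of -0.06 in wild type (exact permutation p = 0.771) and 0.19 in the knockout (exact permutation p = 0.6). FPKM per gene counts reads over the whole gene, so transcript from exons left in place by the deletion would be counted here. Spry4 was higher where Acta2, smooth muscle actin, was higher. Over the 8 knockout libraries the correlation of their log2 levels was r 0.924 (exact permutation p = 0.00196, adjusted over 5 relations 0.00327) and rho 0.952 (exact permutation p = 0.00114), and r was 0.787 without the 2 libraries farthest from the median. Over the 8 wild-type libraries r was 0.760 (exact permutation p = 0.0224, adjusted 0.0281) and rho 0.762 (exact permutation p = 0.0368), with r 0.560 without the 2 farthest. Each set of library numbers held only 4 libraries of a genotype, too few for a correlation.

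**Figure D1:**
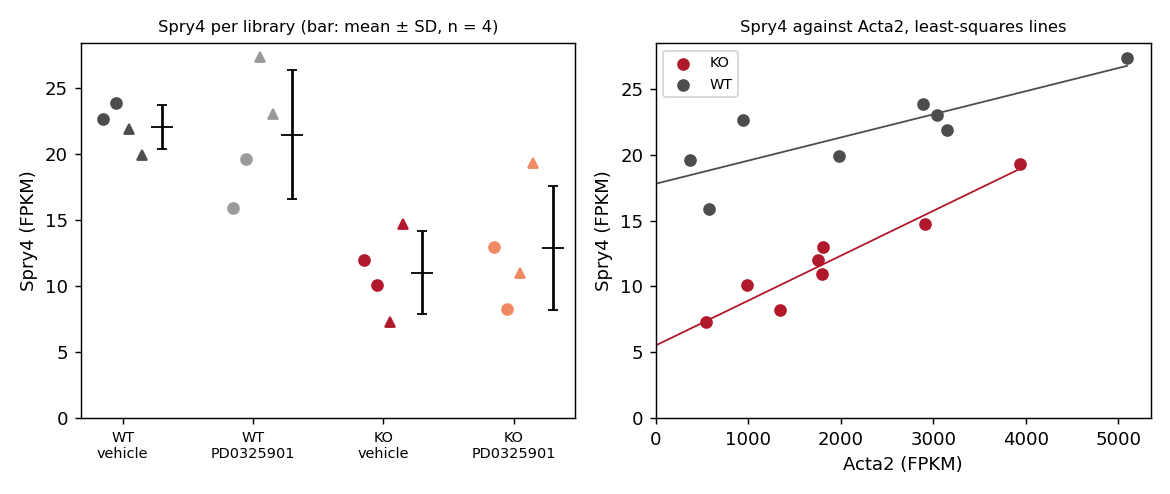
Left, Spry4 in FPKM (vertical axis) in each library of the 4 groups, with circles for the lower 8 library numbers, triangles for the higher 8, and bars for the mean ± SD; the 4 vehicle-treated knockout libraries sit below all 8 wild-type libraries. Right, Spry4 against Acta2, both in FPKM, for the 8 knockout (red) and 8 wild-type (grey) libraries with least-squares lines, which meet the vertical axis at 5.53 FPKM in the knockout and 17.8 FPKM in wild type.

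The sorted fractions carried abundant germ cell transcripts. Zbtb16, a transcription factor of undifferentiated spermatogonia, ranged from 85.6 to 125 FPKM over the 16 libraries, and the germ cell RNA helicase Ddx4 from 68.8 to 144 FPKM. Kit, a receptor of differentiating spermatogonia, averaged 2.34 ± 0.411 FPKM (SD, n = 4) in wild type with vehicle. Transcripts of contractile cells differed far more between libraries than any germ cell gene just named. Acta2 (ENSMUSG00000035783, chromosome 19, 34241090 to 34255590, minus strand) ranged from 367 to 5095 FPKM, a 13.9-fold span, and Myh11, smooth muscle myosin, from 137 to 1270 FPKM. Listed peritubular myoid transcripts took 0.576% to 4.31% of a library's total FPKM. Of the 10 members measured beside Acta2, 6 followed it closely over the libraries (Myh11, Tagln, Des, Cnn1, Myl9 and Tpm2, lowest r 0.962, lowest rho 0.974, permutation p = 1e-05, the smallest possible), and the lowest of these r within either set of 8 library numbers was 0.961. The matrix and fibroblast members did not all follow: r was -0.58 for Pdgfra, -0.28 for Col1a1, -0.20 for Col3a1 and 0.70 for Col1a2, and Dcn reached at most 0.50 FPKM. Mcam, a member of the stem cell list at a mean of 329 FPKM, also followed Acta2 (r 0.956, rho 0.959, permutation p = 1e-05), a relation chosen after its values were seen. Replicate 3 of the vehicle-treated knockout stood apart in spermatid transcripts, with Prm1 at 739 FPKM, Prm2 at 874 FPKM and Tnp2 at 512 FPKM, and a spermatid list mean of 6.44 against 0.210 to 2.92 in the other libraries. Of the other cell types, the Leydig list had 4 measured members and group means of 2.23 to 2.48. Its single libraries ran from 1.35 to 3.55 in step with the peritubular list (r 0.950, rho 0.979, permutation p = 1e-05, r 0.936 without the 2 libraries farthest from the median, examined after the values were seen). The macrophage and leukocyte list had 3 measured members and group means of 1.10 to 1.40, and no erythrocyte gene passed the filter. The table held only 5 of 12 listed Leydig genes and 2 of 8 listed erythrocyte genes, so the absence of the others says nothing about these cells.

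The mean level of 15 of the 26 other tested lists followed the peritubular list over the 16 libraries at an adjusted p of r under 0.05, 13 of them with a size of r above 0.7, a relation examined after the values were seen. The correlation was positive for p53 targets (r 0.909, rho 0.847), quiescence and FOXO targets (0.891 and 0.912), apoptosis regulators (0.879 and 0.897), retinoic acid response (0.869 and 0.850), oxidative phosphorylation (0.868 and 0.879), ERK pathway output (0.845 and 0.826), glycolysis (0.844 and 0.868), immediate early genes (0.805 and 0.815), ATF4 targets (0.805 and 0.829) and Sertoli cell genes (0.668 and 0.638). It was negative for homologous recombination repair (-0.89 and -0.89), the pan-undifferentiated list (-0.84 and -0.84), meiotic genes (-0.82 and -0.81), ribosome biogenesis (-0.74 and -0.73) and DNA replication (-0.65 and -0.68). For these 15 lists the permutation p of r adjusted over 26 was at most 0.0118, and without the 2 libraries farthest from the median r kept its sign, from 0.723 to 0.910 for the positive lists and from -0.53 to -0.90 for the negative ones. Within the lower 8 library numbers r was weaker for immediate early genes (0.430) and ATF4 targets (0.383) than within the higher 8 (0.960 and 0.932), and for Sertoli cell genes it was 0.873 within the lower 8 and 0.155 within the higher 8. The stem cell list (r -0.10, rho -0.13, permutation p = 0.724) and the cholesterol synthesis list (r -0.25, rho -0.23, permutation p = 0.358) showed no such relation. The peritubular list itself did not separate the groups: the 4 groups accounted for 6.47% of its variance (permutation p = 0.834). The first principal component of all tested genes held 52.7% of the variance, and 7 of the 11 measured peritubular members were among its top 100 genes. Many genes thus varied along 1 axis. Lists drawn at random were not compared, so following the peritubular list is not shown to be particular to these 15 lists.

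**Figure D2:**
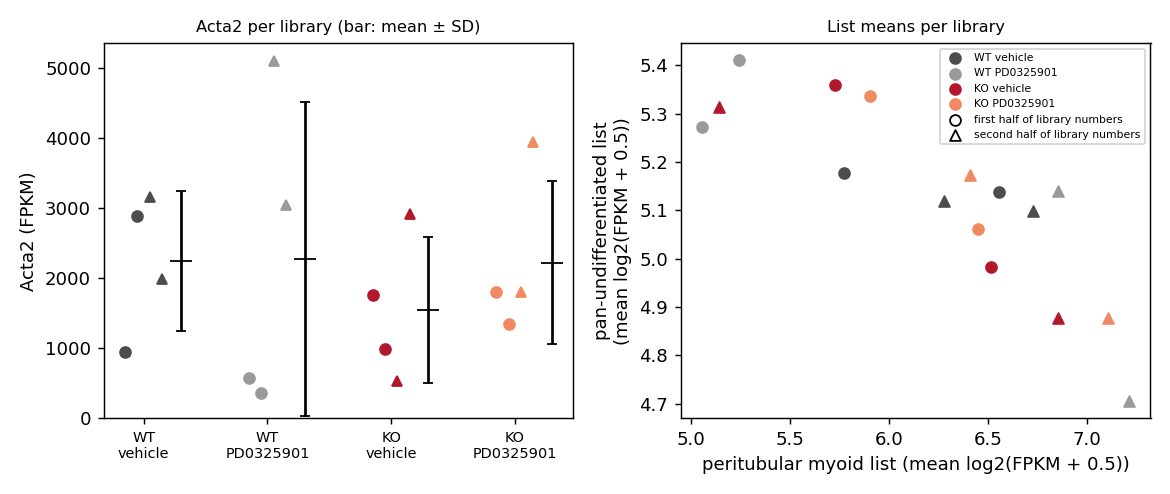
Left, Acta2 in FPKM in each library of the 4 groups, with bars for the mean ± SD; the libraries span 367 to 5095 FPKM and the groups overlap. Right, mean log2(FPKM + 0.5) of the pan-undifferentiated list (vertical axis) against that of the peritubular myoid list (horizontal axis) for the 16 libraries, coloured by group and with triangles for the higher 8 library numbers; the first falls as the second rises (r -0.84).

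With vehicle, the knockout differed from wild type in no single gene past the threshold. Etv5 (ENSMUSG00000013089, chromosome 16, 22381309 to 22439719), an ERK-dependent transcription factor that maintains spermatogonial stem cells, was 47.1 ± 7.51 FPKM (SD, n = 4) in wild type and 57.4 ± 6.26 FPKM in the knockout (log2 difference 0.29, SE 0.13), and Dusp6 (ENSMUSG00000019960, chromosome 10, 99263231 to 99267489), a phosphatase of ERK, was 42.3 ± 7.57 and 51.1 ± 0.201 FPKM (0.29, SE 0.15). Stem cell markers Gfra1 (-0.16, SE 0.16) and Nanos2 (-0.17, SE 0.16), the progenitor factor Neurog3 (0.10, SE 0.28), Kit (-0.07, SE 0.23), Zbtb16 (0.00, SE 0.11), the proliferation marker Mki67 (-0.16, SE 0.15) and the cell cycle inhibitor Cdkn1a (-0.66, SE 0.48) differed by no more than the spread between replicates. The 5 genes with the smallest p, none significant, were Spry4, Msl3l2 (log2 difference -0.41), Rfx8 (1.30), Dpep1 (0.77) and Nubpl (0.39). Rfx8 (ENSMUSG00000057173, chromosome 1, 39665301 to 39720997), a transcription factor of the RFX family, was 0.893 ± 0.333 FPKM in wild type and 2.89 ± 0.535 FPKM in the knockout.

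In the same comparison 12 of 27 lists passed camera at the preset correlation. The stem cell list was higher in the knockout (13 of 17 members higher, mean log2 difference 0.15, adjusted p = 0.00296), with Shisa6 (0.53), Ret (0.27), the receptor for GDNF, and Tcl1 (0.36) as examples. The GDNF-responsive list, which shares Etv5 and other members with it, was higher too (11 of 13 members, adjusted p = 0.00102), as was the endothelial list (8 of 9, adjusted p = 2.28e-05), in which Cdh5, vascular cadherin, was 1.91 ± 0.496 FPKM in wild type and 3.85 ± 2.04 FPKM in the knockout. Immediate early genes were lower as a group (12 of 14 members, mean log2 difference -0.58, adjusted p = 1.31e-05), among them Btg2 (-1.08) and Fosb (-0.91). Oxidative phosphorylation was lower in 17 of 17 members by a mean of only -0.13 (adjusted p = 0.00296), and retinoic acid response in 7 of 7 by -0.32 (adjusted p = 0.00413), with Cyp26a1, which degrades retinoic acid, at -0.43. The other lower lists were p53 targets (16 of 18), quiescence and FOXO targets (11 of 15), ATF4 targets (11 of 15), glycolysis (14 of 16), the mitotic cell cycle (14 of 16) and cholesterol synthesis (13 of 16, adjusted p = 7.9e-05, with Lss at -0.23 and Fdps at -0.34). With an estimated correlation none of the 12 passed, with adjusted p = 0.0637 for the endothelial list and adjusted p up to 0.741 for the others. The peritubular list stood lower in these knockout libraries by a mean log2 of -0.27 (exact permutation p = 0.571), and 7 of the 9 lower lists were among those that rose with it.

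Leaving out 1 library ended the call of 8 of these 12 lists, and the GDNF-responsive, endothelial, immediate early and retinoic acid lists kept theirs. For the stem cell list it ended without WT_vehicle 1 (0.11), WT_vehicle 2 (0.05) or KO_vehicle 4 (0.06), and stood at 0.24 without WT_vehicle 4 and 0.22 without KO_vehicle 1. The call ended without WT_vehicle 3 for oxidative phosphorylation (-0.05) and glycolysis (-0.12), and without WT_vehicle 4 for p53 targets (-0.25), ATF4 targets (-0.17) and the mitotic list (-0.02). It ended without KO_vehicle 1 for the mitotic list (0.01), ATF4 targets (-0.14), glycolysis (-0.14) and cholesterol synthesis (-0.07), without KO_vehicle 3 for ATF4 targets (-0.12) and FOXO targets (-0.14), and without KO_vehicle 4 for the mitotic list (-0.05). Calls that held still moved. Without KO_vehicle 4 immediate early genes were at -0.90, FOXO targets at -0.39 and oxidative phosphorylation at -0.20, and without WT_vehicle 1 oxidative phosphorylation was at -0.23 and the mitotic list at -0.13. The mitotic list was at -0.18 without KO_vehicle 3, and the GDNF-responsive list at 0.09 without WT_vehicle 2 and 0.26 without WT_vehicle 4. Without both WT_vehicle 4 and WT_PD 4 the p53 and mitotic calls ended. With the peritubular and spermatid list means as terms, chosen after the data were seen, all 12 lists kept their call, at means of -0.19 for p53 targets, -0.15 for FOXO targets, -0.09 for glycolysis and -0.06 for oxidative phosphorylation. With these terms 4 more lists passed: progenitor (-0.13, adjusted p = 0.0480), ERK pathway output (0.09, adjusted p = 0.0373), DNA replication (-0.09, adjusted p = 0.00338) and ribosome biogenesis (-0.07, adjusted p = 0.0152). The first 2 of these had adjusted p = 0.0756 with the library-number set as a further term.

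By limma, 0 of 12907 genes passed the adjusted threshold for this comparison, 251 had an unadjusted p under 0.05 where chance alone gives 645, and limma's voom on recovered reads also gave 0. The libraries of the groups did not overlap for 189 genes (1.46%, where chance gives 2.86%). No member of any list passed when adjusted over the list alone.

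In wild type 10 days after busulfan, Etv5 and Dusp6 stood near their vehicle levels with PD0325901. That was the only time sampled, so their levels during the course of daily injections are not known. Etv5 was 42.1 ± 5.87 FPKM (SD, n = 4) with inhibitor (log2 difference -0.16, SE 0.13), Dusp6 39.6 ± 8.22 FPKM (-0.10, SE 0.15), Gfra1 41.7 ± 7.40 FPKM (-0.19, SE 0.16) and Neurog3 5.34 ± 1.99 FPKM against 3.66 ± 0.656 (0.44, SE 0.28). Nanos2 (-0.21), Kit (0.16), Zbtb16 (-0.06), Mki67 (-0.09) and Cdkn1a (-0.19) also stayed within the spread. The 5 genes with the smallest p, none significant, were Cables1 (log2 difference 0.70), the RNase P subunit gene Rpp38 (-0.27), the homeobox gene Barx1 (-0.79), Nfatc2 (-0.34) and Cfap92 (-0.42).

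The stem cell list was lower with inhibitor in wild type (16 of 17 members, mean log2 difference -0.28, adjusted p = 2.96e-14), with Lhx1 (ENSMUSG00000018698, chromosome 11, 84518284 to 84525535) going from 8.68 ± 3.57 to 5.09 ± 0.916 FPKM (-0.66), T at -0.60 and Eomes at -0.47; the GDNF-responsive list, which holds all 3, was lower in 12 of 13 members (adjusted p = 2.9e-08). With an estimated correlation both had adjusted p = 0.247. The progenitor list was higher in 9 of 10 members (mean 0.18, adjusted p = 0.00377), with Sox3 at 0.23 and Rarg at 0.19, and had adjusted p = 0.480 with an estimated correlation. Immediate early genes were lower in 14 of 14 members (mean -0.31, adjusted p = 2.41e-06), and Egr1, a rapid target of ERK signalling, was 156 ± 29.7 FPKM with vehicle and 103 ± 10.0 FPKM with inhibitor (-0.58) without overlap of libraries. This list had adjusted p = 0.480 with an estimated correlation. At higher p, lists also passed for spermatid genes (10 of 10 lower, mean -0.57), p53 targets (11 of 18 lower), retinoic acid response (6 of 7 lower, mean -0.23), cholesterol synthesis (12 of 16 lower), DNA replication (15 of 18 lower) and the mitotic cell cycle (11 of 16 lower), with preset adjusted p from 0.0173 to 0.0441 and adjusted p from 0.480 to 0.938 with an estimated correlation. The peritubular list stood lower in the inhibitor-treated libraries by a mean log2 of -0.24 (exact permutation p = 0.714), and 3 of the 9 lower lists were among those that rose with it, while DNA replication was among those that fell.

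Only the stem cell, GDNF-responsive and immediate early lists kept this call without each single library, and 7 of the 10 lost it. Without WT_vehicle 4 the stem cell list was at -0.19 and the GDNF-responsive list at -0.15. Immediate early genes were at -0.11 without WT_PD 1, -0.12 without WT_PD 2 and -0.58 without WT_PD 3. The progenitor call ended without WT_vehicle 4 (0.10) or WT_PD 1 (0.07), and the mean was 0.28 without WT_PD 3. For p53 targets it ended without WT_vehicle 4 (-0.10), WT_PD 1 (-0.04) or WT_PD 2 (0.03), with -0.22, -0.28 and -0.25 without WT_vehicle 1, WT_PD 3 and WT_PD 4. Retinoic acid response lost it without WT_vehicle 2 (-0.17), WT_vehicle 3 (-0.13), WT_PD 1 (-0.07) or WT_PD 2 (-0.04), with -0.41 and -0.39 without WT_PD 3 and WT_PD 4. Cholesterol synthesis lost it without WT_vehicle 1 (-0.04), WT_vehicle 2 (-0.04), WT_vehicle 3 (-0.01), WT_PD 2 (-0.02) or WT_PD 3 (-0.04), with -0.09 without WT_vehicle 4. DNA replication lost it without WT_vehicle 4 (-0.01) or WT_PD 3 (0.03), the library with the most Acta2, with -0.10 without WT_PD 2. The mitotic list lost it without WT_vehicle 2 (-0.04), WT_vehicle 4 (0.02) or WT_PD 3 (0.04), with -0.10 without WT_vehicle 1 and -0.09 without WT_vehicle 3, WT_PD 2 or WT_PD 4. Spermatid genes lost it without WT_vehicle 1 (-0.33), WT_vehicle 4 (-0.40), WT_PD 1 (-0.21), WT_PD 3 (-0.74) or WT_PD 4 (-0.26), with -1.03 and -1.06 without WT_vehicle 2 and WT_PD 2. Without both WT_vehicle 4 and WT_PD 4 the call ended for 6 of the 10, the GDNF-responsive list among them. With the content terms it ended for the progenitor list (0.10, adjusted p = 0.355), p53 targets (-0.05, adjusted p = 0.185) and retinoic acid response (-0.10, adjusted p = 0.185), and the spermatid list, being a term, could not be tested. The means of lists that kept it were -0.18 for immediate early genes, -0.10 for the mitotic list, -0.09 for DNA replication and -0.08 for cholesterol synthesis. With these terms 4 more lists passed: pan-undifferentiated (-0.09, adjusted p = 0.00102), homologous recombination (-0.08, adjusted p = 0.000242), meiotic (-0.05, adjusted p = 0.0391, or 0.144 with the library-number set added) and mitochondrially encoded (0.37, adjusted p = 0.0413).

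By limma, 0 of 12907 genes passed the threshold for inhibitor against vehicle in wild type, 115 had an unadjusted p under 0.05, voom on recovered reads gave 0, and 85 genes had no overlap between the groups (0.659%, where chance gives 2.86%). No list member passed when adjusted over the list alone.

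In the knockout, the inhibitor was likewise followed by small shifts in the named genes. Etv5 was 51.2 ± 4.37 FPKM (SD, n = 4) with inhibitor (log2 difference -0.16, SE 0.13) and Dusp6 45.8 ± 6.62 FPKM (-0.17, SE 0.15). The ERK-dependent factor Etv4, an example picked from the ERK pathway output list, was 22.9 ± 2.66 FPKM with vehicle and 30.8 ± 5.14 FPKM with inhibitor (0.41, SE 0.14). Neurog3 was 4.18 ± 1.80 and 6.18 ± 1.52 FPKM (0.57, SE 0.28). Gfra1 (-0.23), Nanos2 (0.15), Kit (0.13), Zbtb16 (0.06), Mki67 (0.18) and Cdkn1a (0.50) lay within the spread. The 5 genes with the smallest p, none significant, were Rfx8 (log2 difference -1.39, from 2.89 ± 0.535 to 0.797 ± 0.225 FPKM), Tsn (-0.30), Zdhhc15 (-0.53), Cgnl1 (-0.60) and Dmrt2 (-0.86, from 16.6 ± 2.84 to 9.01 ± 2.01 FPKM).

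In this comparison 10 lists passed at the preset correlation. Retinoic acid response was higher in 7 of 7 members (mean log2 difference 0.39, adjusted p = 0.00366), with Cyp26a1 and Stra8, a gene induced as spermatogonia enter differentiation, both at 0.51, and had adjusted p = 0.174 with an estimated correlation. When adjusted over the list alone, Cyp26a1 passed as its only member; over all genes it did not. The progenitor list was higher in 7 of 10 members (adjusted p = 0.0159), with Rarg at 0.31, and the DNA replication list in 14 of 18 (adjusted p = 0.0312), with Tyms at 0.20. Immediate early genes (11 of 14 members), p53 targets (16 of 18), ATF4 targets (13 of 15, with Phgdh, an enzyme of serine synthesis, at 0.34), glycolysis (14 of 16) and oxidative phosphorylation (16 of 17) were also higher. The endothelial list was lower in 8 of 9 members (mean -0.39, adjusted p = 0.00366), with Cdh5 at -0.57, and cholesterol synthesis in 14 of 16 (mean -0.09, adjusted p = 0.0223). With an estimated correlation none of the 10 passed, at adjusted p = 0.174 for the endothelial list and adjusted p up to 0.688 for the others. The peritubular list stood 0.41 higher on the log2 scale in these inhibitor-treated libraries (exact permutation p = 0.4), and 6 of the 8 higher lists were among those that rose with it, while DNA replication was among those that fell.

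Retinoic acid response and the endothelial list kept this call without each single library, the latter at -0.25 without KO_vehicle 3, and the other 8 of the 10 lost it. Immediate early genes lost it without KO_vehicle 1 (0.17), KO_vehicle 3 (0.16), KO_PD 1 (0.34), KO_PD 3 (0.30) or KO_PD 4 (0.18), and were at 0.64 without KO_vehicle 4. For p53 targets it ended without KO_vehicle 2 (0.17), KO_vehicle 3 (0.14), KO_PD 1 (0.21) or KO_PD 3 (0.22), with 0.35 without KO_vehicle 4. DNA replication lost it without KO_vehicle 1 (0.00), KO_vehicle 4 (0.03), KO_PD 2 (0.00) or KO_PD 3 (0.05), with 0.13, 0.10 and 0.10 without KO_vehicle 3, KO_PD 1 and KO_PD 4. Oxidative phosphorylation lost it without KO_vehicle 1 (0.08), KO_vehicle 2 (0.07), KO_vehicle 3 (0.09) or KO_PD 4 (0.02), with 0.18 without KO_vehicle 4. ATF4 targets lost it without KO_vehicle 1 (0.13) or KO_vehicle 3 (0.12), with 0.10 without KO_PD 4. The progenitor call ended without KO_vehicle 4 (0.11) or KO_PD 3 (0.15), and that of glycolysis without KO_PD 4 (0.04), with 0.22 without KO_vehicle 4. Cholesterol synthesis lost it without KO_vehicle 2 (-0.03), KO_PD 1 (-0.07) or KO_PD 4 (-0.07), with -0.15 and -0.14 without KO_vehicle 1 and KO_PD 2. With the content terms 5 of the 10 calls ended: immediate early genes (0.07, adjusted p = 0.360), p53 targets (0.07, adjusted p = 0.0920), glycolysis (0.03, adjusted p = 0.175), oxidative phosphorylation (0.00, adjusted p = 0.925) and cholesterol synthesis (-0.09, adjusted p = 0.143). Retinoic acid response (0.24), ATF4 targets (0.09) and DNA replication (0.12) kept theirs at other sizes. The mitotic list (0.13, adjusted p = 0.00121), ribosome biogenesis (0.07, adjusted p = 0.00121) and differentiating spermatogonia (0.06, adjusted p = 0.0339) passed only with these terms.

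By limma, 0 of 12907 genes passed for inhibitor against vehicle in the knockout, 382 had an unadjusted p under 0.05, voom on recovered reads gave 0, and 220 genes did not overlap between the groups (1.70%, where chance gives 2.86%).

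Under inhibitor, the knockout and wild type had the lowest preset p in the stem cell and GDNF-responsive lists. The stem cell list was higher in the knockout in 16 of 17 members (mean log2 difference 0.31, adjusted p = 4.41e-09), with Lhx1 at 5.09 ± 0.916 FPKM in wild type and 8.65 ± 1.67 FPKM in the knockout (SD, n = 4, log2 difference 0.71, no overlap), Bcl6b at 0.38 and Pdx1 at 0.43. The GDNF-responsive list was higher in 12 of 13 members (mean 0.29, adjusted p = 5.6e-08), with Egr2 at 25.4 ± 4.40 and 36.4 ± 4.74 FPKM (0.52, no overlap). Both lists had adjusted p = 0.436 with an estimated correlation. Every library mean of the stem cell list in the knockout lay above every one in wild type (exact permutation p = 0.0286, adjusted over 27 lists 0.771, both the lowest that 1 list alone can reach), by 0.23 among the lower 8 library numbers and 0.39 among the higher 8. The peritubular list stood 0.38 higher on the log2 scale in these knockout libraries (exact permutation p = 0.514).

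Cholesterol synthesis genes were lower in the inhibitor-treated knockout in 16 of 16 members (mean log2 difference -0.17, adjusted p = 3.9e-05), led by Cyp51 (-0.42), Sc5d (-0.30) and Msmo1 (-0.28), with adjusted p = 0.534 with an estimated correlation. This call ended with the content terms (-0.13, adjusted p = 0.155), and with the library-number set added (adjusted p = 0.295). Mitochondrially encoded transcripts were lower in 12 of 12 (mean -0.48, adjusted p = 0.00132), with mt-Nd2 at 1682 ± 124 FPKM in wild type and 1312 ± 423 FPKM in the knockout, and DNA replication genes were higher in 14 of 18 (mean 0.06, adjusted p = 0.0297). These 2 lists had adjusted p = 0.918 with an estimated correlation. The mitochondrial call ended without KO_PD 3 (-0.26, adjusted p = 0.110), and the replication call without WT_PD 3 (-0.02), KO_PD 2 (0.00) or KO_PD 3 (0.04), with 0.11, 0.10 and 0.09 without WT_PD 2, KO_PD 1 and KO_PD 4. With the content terms the replication mean was 0.12, and the pan-undifferentiated list (0.11, adjusted p = 0.00349), homologous recombination (0.05, adjusted p = 0.0191, or 0.144 with the library-number set added) and the mitotic list (0.10, adjusted p = 0.0129) passed too. Among the named genes, Etv5 was 42.1 ± 5.87 and 51.2 ± 4.37 FPKM (0.28, SE 0.13) and Dusp6 39.6 ± 8.22 and 45.8 ± 6.62 FPKM (0.22, SE 0.15). Etv4, an example picked from the ERK pathway output list, was 22.9 ± 2.68 and 30.8 ± 5.14 FPKM (0.41, SE 0.14). Gfra1 (-0.20), Nanos2 (0.19), Neurog3 (0.23), Kit (-0.10), Zbtb16 (0.12), Mki67 (0.11) and Cdkn1a (0.03) lay within the spread. The 5 genes with the smallest p, none significant, were Nfatc2 (log2 difference 0.43), Crygs (0.56), Smoc1 (0.43), Ugcg, the gene of glucosylceramide synthase (-0.39), and Sp6 (0.68, from 5.04 ± 0.328 to 8.44 ± 1.28 FPKM).

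By limma, 0 of 12907 genes passed for knockout against wild type under inhibitor, 605 had an unadjusted p under 0.05 (207 higher and 398 lower in the knockout), and voom on recovered reads gave 0. The unadjusted count was 4302 with library weights, 2266 with the peritubular list mean as a term, and 262 (without KO_PD 4) to 944 (without KO_PD 1) with 1 library left out, and 0 genes passed the threshold in each of these. The libraries of the groups did not overlap for 294 genes (2.28%, where chance gives 2.86%). No list member passed when adjusted over the list alone.

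**Figure D3:**
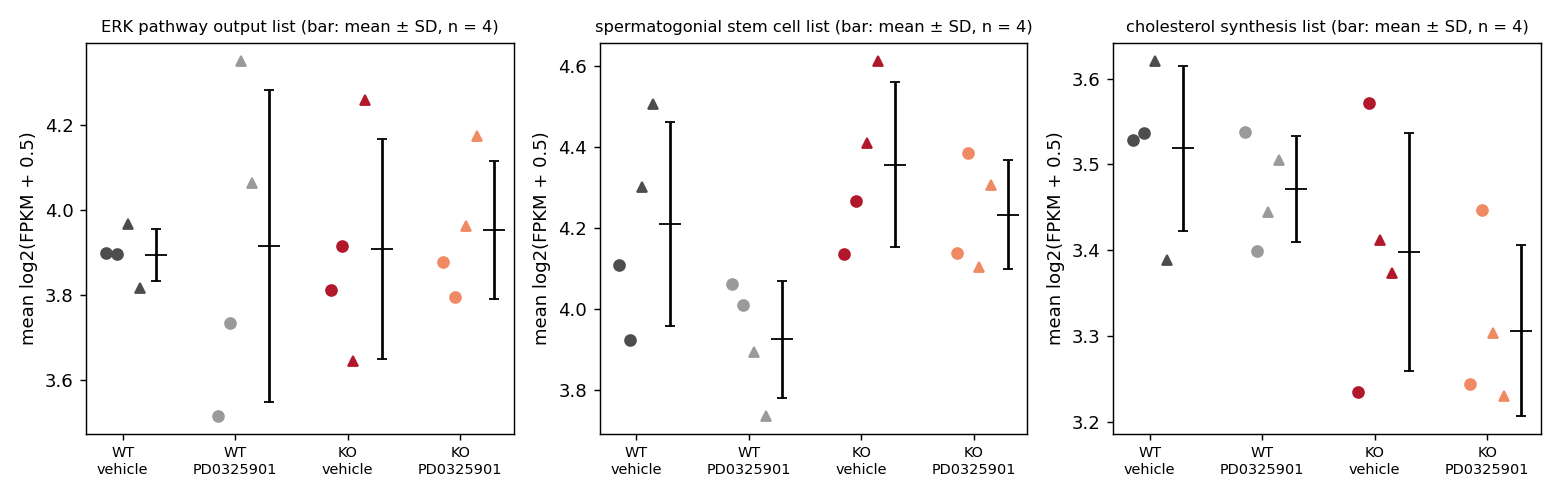
Mean log2(FPKM + 0.5) per library (vertical axes) of the ERK pathway output, stem cell and cholesterol synthesis lists in the 4 groups, with circles for the lower 8 library numbers, triangles for the higher 8, and bars for the mean ± SD; the ERK means overlap in all groups, and the 4 inhibitor-treated knockout libraries lie above the 4 inhibitor-treated wild-type libraries in the stem cell list.

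The ERK pathway output list, 18 genes that respond to the pathway between MEK and transcription, passed in no comparison in the fit without terms. Cells were collected at a single time, after the course of daily injections, and ERK activity itself was not measured. The values therefore cannot say whether ERK output was lower while the inhibitor was being given. Its mean was 3.89 ± 0.0614 (SD, n = 4) in wild type with vehicle, 3.92 ± 0.366 in wild type with inhibitor, 3.91 ± 0.258 in knockout with vehicle and 3.95 ± 0.163 in knockout with inhibitor. The log2 differences were 0.01 and 0.04 for knockout against wild type under vehicle and inhibitor, and 0.02 and 0.05 for inhibitor against vehicle in wild type and knockout, with exact permutation p from 0.8 to 0.914 (all 4 adjusted to 0.914). With the peritubular and spermatid list means as terms the list passed camera for knockout against wild type under vehicle (0.09, adjusted p = 0.0373), but not with the library-number set added (adjusted p = 0.0756). The list's mean followed the peritubular list, as given above (r 0.605 within the lower 8 library numbers and 0.905 within the higher 8).

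The effect of the inhibitor was compared between genotypes by the interaction term. The most divergent genes, none significant, were Rfx8 (interaction log2 -1.82, SE 0.46), Msl3l2 (0.56), Timp1, an inhibitor of matrix metalloproteinases (0.67), Tsn (-0.37) and Capn12 (0.72). For Etv5 the interaction was 0.00 (SE 0.18), for Dusp6 -0.07 (SE 0.21) and for Spry4 0.26 (SE 0.34). Gfra1 (-0.04), Nanos2 (0.36, SE 0.23), Neurog3 (0.13), Kit (-0.03), Zbtb16 (0.12), Mki67 (0.27, SE 0.21) and Cdkn1a (0.70, SE 0.68) had 95% confidence intervals that included 0. At the preset correlation 10 lists passed, where libraries regrouped at random gave a median of 9. The 10 were led by immediate early genes (14 of 14 members positive, mean 0.63, adjusted p = 2.76e-05) and retinoic acid response (7 of 7, mean 0.62, adjusted p = 0.000334). With an estimated correlation none passed, with adjusted p = 0.507 for the first and adjusted p = 0.134 for the second. Without KO_vehicle 4 the first had a mean of 0.95. With the content terms the means were 0.26 for the first (adjusted p = 0.00674) and 0.33 for the second (adjusted p = 0.00374). By limma, 0 of 12907 genes passed for the interaction, 1.71% had an unadjusted p under 0.05, and voom on recovered reads gave 0.

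Compared with vehicle-treated wild type, the inhibitor-treated knockout had lower cholesterol synthesis genes. All 16 members were lower (mean log2 difference -0.21, adjusted p = 5.75e-13), among them Lss (ENSMUSG00000033105, chromosome 10, 76531588 to 76557138), the gene of lanosterol synthase, at 7.81 ± 0.657 and 6.32 ± 0.0576 FPKM (SD, n = 4, log2 difference -0.28), Msmo1 (-0.34), Cyp51 (-0.40) and Idi1 (-0.39). The list had adjusted p = 0.209 with an estimated correlation. When adjusted over the list alone, Lss was the only member to pass; over all genes it did not. It was the only list to pass at the preset correlation. With the content terms it passed as well (-0.21, adjusted p = 4.75e-07), and so did immediate early genes (-0.34, adjusted p = 0.0117) and FOXO targets (-0.15, adjusted p = 0.0325). Between these groups the peritubular list differed by 0.13 (exact permutation p = 0.714). The 5 genes with the smallest p, none significant, were Lss, Npw (0.71), Spry4 (-0.82), the copper transporter gene Slc31a1 (-0.27) and Scd1, a fatty acid desaturase gene (-0.44). Gfra1 was 47.9 ± 11.1 and 36.0 ± 5.11 FPKM (-0.39, SE 0.16), and Neurog3 3.66 ± 0.656 and 6.18 ± 1.52 FPKM (0.67, SE 0.28, no overlap). Etv5 (0.13), Dusp6 (0.12), Nanos2 (-0.02), Kit (0.06), Zbtb16 (0.06), Mki67 (0.02) and Cdkn1a (-0.16) lay within the spread. By limma, 0 of 12907 genes passed, 195 had an unadjusted p under 0.05, voom on recovered reads gave 0, and 157 genes did not overlap (1.22%, where chance gives 2.86%).

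Whether the inhibitor turns back the differences of the knockout could be examined only across all genes, because no gene passed in the vehicle comparison. Across 12907 genes, which are not independent replicates, the knockout difference under vehicle and the inhibitor difference in the knockout had r = -0.76, and 71.9% of genes had opposite signs. Both differences use the same 4 vehicle-treated knockout libraries. For comparison, the residuals of whole libraries, with group means removed, were dealt to the groups at random in 100 draws. There r averaged -0.46, the middle 95% of draws lay from -0.89 to 0.38, and 43 of 100 draws were as far from that average. The covariance was -0.0359 against a mean of -0.0351 in the draws. With those 4 libraries split between the differences r lay between -0.23 and 0.28 in 6 splits. The inhibitor differences in wild type and in the knockout, which share no library, had r = -0.30 (middle 95% of draws from -0.63 to 0.74). The knockout differences under vehicle and under inhibitor had r = -0.07 (middle 95% of draws from -0.75 to 0.67). In each of these pairs 0 genes were called in both, with 0 expected by chance from the limma counts of 0.

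Of the 27 lists tested, 11 passed in no comparison in the fit with all libraries and no terms. Without WT_vehicle 4 and WT_PD 4 the peritubular list passed for knockout against wild type under inhibitor and for the interaction. With content terms 6 of the 11 passed somewhere, as given above: pan-undifferentiated, differentiating, meiotic, homologous recombination, ribosome biogenesis and ERK pathway output. With the library-number set added, meiotic genes and ERK pathway output passed in none. Apoptosis regulators, interferon response, heat shock and Sertoli cell genes passed in none, and the peritubular list, being a term, could not be tested there. Over the comparisons of 2 groups other than inhibitor-treated knockout with vehicle-treated wild type, their mean log2 differences ranged from -0.02 to 0.00 for the pan-undifferentiated list, from -0.04 to 0.08 for differentiating spermatogonia, from -0.18 to 0.03 for meiotic genes, from -0.09 to 0.03 for homologous recombination and crosslink repair and from -0.07 to 0.01 for apoptosis regulators. They ranged from -0.05 to 0.03 for ribosome biogenesis, from -0.12 to 0.02 for interferon response, from -0.06 to 0.00 for heat shock and dissociation stress, from -0.05 to 0.08 for Sertoli cell genes, and from -0.27 to 0.41 for peritubular myoid genes. The remaining one was the ERK pathway output list. Of the 162 list tests, 48 passed at the preset correlation, with mean, median and test of one sign in each; in 26 of the others these signs differed.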

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

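The tests of the 3 patterns weighed here, the content terms and the lists without single libraries were all chosen after the results were seen, while the counts over other splits of the libraries were planned, except for the fit with 3 terms.

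Peritubular myoid transcripts differed between libraries of the same group, with Acta2 from 367 to 5095 FPKM. RNA from smooth-muscle-like cells in the sorted fraction is a candidate source, since 6 of 10 members followed Acta2 closely, but not of the whole list: the median correlation of pairs was 0.543, 45.5% of pairs lay below 0 (lowest -0.61), and Pdgfra, Col1a1 and Col3a1 did not follow. The lower and higher library numbers held 25.2% of the variance of the list mean (exact permutation p = 0.050), with a range of 2.07 within a single set against 2.16 over all, which argues against library number as the whole source. The 4 groups held 6.47% (permutation p = 0.834), which argues against genotype or inhibitor as the main source. Which cells carried the transcripts, and whether germ cells expressed any of them, stays open.

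Spry4 stayed at 11.0 FPKM in the vehicle-treated knockout. If the deletion was confined to germ cells, cells with smooth muscle transcripts would keep the gene and may supply part of this Spry4. Its level rose with Acta2 over the 8 knockout libraries (r 0.924, exact permutation p = 0.00196). The line through these libraries met zero Acta2 at 5.53 FPKM (5.02 to 6.08 without each library), against 17.8 FPKM in wild type, or 31.1%. That remainder may come from germ cells that escaped deletion or from the part of the gene left in place, and gene-level FPKM cannot part them.

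The stem cell list was higher in the inhibitor-treated knockout than in inhibitor-treated wild type. In 5 of the 35 splits of these 8 libraries, the real one included, some list had a camera p as low, so chance over the 27 lists could account for it. The splits were not limited to those balanced over the library numbers, as the real grouping is. With peritubular and spermatid list means as terms the difference was 0.32 (-0.01 to 0.66) against 0.31 without them, and the part these means carried was -0.01 (-0.12 to 0.09), which argues against peritubular content as the whole source, although the interval of 0.32 reaches below 0. Against library number as the source, the difference was 0.23 within the lower 8 numbers and 0.39 within the higher 8. The effect of Spry4 loss under inhibitor stays among the open explanations, as untested.

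For the count of genes in single comparisons, limma gave 0 in the real grouping, a count that every split must reach, so these splits cannot say whether chance is excluded: other splits of the 8 libraries reached 0 for knockout against wild type under vehicle, 2515 for inhibitor in wild type, 0 for inhibitor in the knockout, 3066 for knockout against wild type under inhibitor and 3 for inhibitor-treated knockout against vehicle-treated wild type, with 35 of 35 splits as large in each. For the interaction 100 of 100 splits were as large, and the highest other count was 1. Unadjusted p under 0.05 was found for 251, 115, 382, 605 and 195 genes in these comparisons, and voom gave 0 in each. The split with 2515 genes set replicates 1 and 4 with vehicle and 1 and 2 with inhibitor against the other 4 wild-type libraries. The split with 3066 genes followed the library numbers, and both point to a structure of the samples, with peritubular list means 1.25 and 1.23 apart on the log2 scale.

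For the gene lists called at the preset correlation, chance could not be excluded in any comparison. The real count was 12 for knockout against wild type under vehicle (9 of 35 splits as large, highest other 15), 10 for inhibitor in wild type (16 of 35, highest other 15) and 10 for inhibitor in the knockout (15 of 35, highest other 14). It was 5 for knockout against wild type under inhibitor (30 of 35, highest other 13), 1 for inhibitor-treated knockout against vehicle-treated wild type (35 of 35, highest other 14) and 10 for the interaction (45 of 100, highest other 16). In the same order the other splits called a median of 9, 9, 8, 8, 6.5 and 9 lists. The real count lay below that median under inhibitor and for inhibitor-treated knockout against vehicle-treated wild type. The splits were not limited to those balanced over the library numbers.

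Of 240 groups of 4 values, 11 had a library far from the others, where chance gives about 1 in 20, or 12. Cdkn1a was 18.5 FPKM in replicate 4 of the vehicle-treated knockout, with the others at 6.16 to 7.41 FPKM. Msl3l2 was 6.96 FPKM in replicate 1 of the inhibitor-treated knockout (others 7.52 to 7.63), and Barx1 was 11.9 FPKM in its replicate 4 (others 6.35 to 6.97). Slc31a1 was 8.91 FPKM in replicate 4 of the inhibitor-treated wild type (others 7.22 to 7.38), and Scd1 was 2.30 FPKM in its replicate 3 (others 1.75 to 1.83). In the same replicate 3 the mean of the mitotic cell cycle list was 4.11 (others 4.44 to 4.49) and that of the ribosome biogenesis list 4.94 (others 5.23 to 5.26). In the vehicle-treated knockout the differentiating spermatogonia list was 4.62 in replicate 3 (others 3.33 to 3.53) and the glycolysis list 4.38 in replicate 4 (others 4.03 to 4.05). In replicate 1 of the vehicle-treated wild type the p53 target list was 3.32 (others 3.63 to 3.69) and the mitochondrially encoded list 6.23 (others 6.79 to 6.86).

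Camera on the interaction at the preset correlation called 10 lists, where libraries regrouped at random gave a median of 9. The mean interaction log2 values were 0.16 for the stem cell list (adjusted p = 0.0116), 0.63 for immediate early genes (adjusted p = 2.76e-05), 0.36 for p53 targets (adjusted p = 0.00568), 0.12 for the mitotic cell cycle (adjusted p = 0.0116) and 0.11 for DNA replication (adjusted p = 0.00263). They were 0.21 for ATF4 targets (adjusted p = 0.0109), 0.13 for oxidative phosphorylation (adjusted p = 0.0116), 0.62 for retinoic acid response (adjusted p = 0.000334), -0.36 for mitochondrially encoded transcripts (adjusted p = 0.0289) and -0.49 for endothelial genes (adjusted p = 0.0179). With an estimated correlation none of the 10 passed (adjusted p = 0.134 at the lowest).

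Leaving out 1 library ended the call of 8 of these 10 lists, all but immediate early genes (0.95 without KO_vehicle 4) and retinoic acid response. For the stem cell list it ended without WT_vehicle 4 (0.06), WT_PD 3 (0.15), WT_PD 4 (0.10), KO_vehicle 1 (0.09) or KO_PD 2 (0.11), with 0.26 and 0.25 without WT_vehicle 2 and KO_vehicle 4. The mitotic list lost it without WT_vehicle 4 (0.05), WT_PD 3 (0.03), KO_vehicle 1 (0.03), KO_vehicle 4 (0.08) or KO_PD 2 (0.06), with 0.21 without KO_vehicle 3. DNA replication lost it without WT_PD 3 (0.03), KO_vehicle 1 (0.05) or KO_PD 2 (0.05), with 0.18 without KO_vehicle 3. For p53 targets it ended without WT_vehicle 4 (0.32) or KO_PD 1 (0.35), with 0.19 without WT_PD 2, and for ATF4 targets without WT_PD 3 (0.25). Oxidative phosphorylation lost it without WT_vehicle 3 (0.06), WT_PD 1 (0.03), WT_PD 2 (0.04), KO_vehicle 3 (0.12) or KO_PD 4 (0.05), with 0.24, 0.25, 0.21 and 0.21 without WT_vehicle 1, WT_PD 3, WT_PD 4 and KO_vehicle 4. Endothelial genes lost it without WT_PD 3 (-0.39), KO_vehicle 3 (-0.35) or KO_PD 2 (-0.39). Mitochondrially encoded transcripts lost it without any of 8 libraries, from -0.06 without KO_vehicle 3 to -0.36 without KO_vehicle 1, and kept it at -0.56 and -0.55 without KO_vehicle 4 and KO_PD 2. Without both WT_vehicle 4 and WT_PD 4 the stem cell, mitotic and mitochondrial calls ended.

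With the peritubular and spermatid list means as terms the interaction call ended for oxidative phosphorylation (-0.06, adjusted p = 0.601) and mitochondrially encoded transcripts (-0.40, adjusted p = 0.0880). It held at 0.26 for immediate early genes, 0.33 for retinoic acid response, 0.12 for p53 targets, 0.12 for ATF4 targets, 0.23 for the mitotic list and 0.20 for DNA replication. Passing only with these terms were the pan-undifferentiated list (0.16, adjusted p = 0.00128), the GDNF-responsive list (0.21, adjusted p = 0.00357), ribosome biogenesis (0.09, adjusted p = 0.00357), homologous recombination (0.07, adjusted p = 0.0111) and meiotic genes (0.04, adjusted p = 0.0419). With the library-number set added, the last pair had adjusted p = 0.0730 and adjusted p = 0.206, the endothelial call ended (adjusted p = 0.0946), and the mitochondrial call returned (adjusted p = 0.0411).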

How the results depend on the processing

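Fits with content terms, the fits without 2 libraries, voom, exact permutation of list means, and lists without each library were chosen after the data were seen. By limma 0 genes passed in every comparison under all alternatives, with each library left out included, except knockout against wild type under inhibitor with content terms and library-number set together. That gave 783 genes with peritubular and spermatid terms, 240 with the peritubular term alone, and with both terms 0 (without WT_PD replicate 3) to 927 (without KO_vehicle replicate 3) with 1 library left out. At an unadjusted p under 0.05 there were 115 to 605 genes over the 6 comparisons, and voom on recovered reads gave 0 in each. These unadjusted counts were not stable: they were 514 to 4302 with library weights (the most for knockout against wild type under inhibitor, smallest adjusted p 0.0628), 539 to 3461 with content terms, and 47 to 944 with 1 library left out. Of 1919 values of named genes under alternatives, 1887 moved by less than the spread and 32 by more, at most 0.96 on the log2 scale. Of 1040 list values, 739 kept direction and side of the threshold, 292 fell below it and 9 reversed, counted by the direction of the list test. Means that also changed sign, with the call ended, include p53 targets for inhibitor in wild type (0.031 without WT_PD replicate 2) and the mitotic list under vehicle (0.0053 without KO_vehicle replicate 1). For inhibitor in the knockout they include DNA replication (-2.12e-05 without KO_vehicle replicate 1) and oxidative phosphorylation (-0.0026 with both content terms). The cause of the changes below was not tested.

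With an estimated correlation, with fry, and with exact permutation of list means, 0 lists passed in each of the 6 comparisons. The permutation says little, since between 2 groups of 4 at least 16 lists would have to reach its lowest p together to pass. Without WT_vehicle 4 and WT_PD 4, whose columns have more decimals, 0 genes passed, and of the lists called with all libraries 2 of 12, 6 of 10, 0 of 10, 0 of 5, 3 of 10 and 0 of 1 lost the call (vehicle, inhibitor in wild type, inhibitor in the knockout, under inhibitor, interaction, and inhibitor-treated knockout against vehicle-treated wild type). The lists called then numbered 12, 5, 11, 7, 9 and 4, with stem cell, immediate early and GDNF-responsive added in the last, retinoic acid and peritubular under inhibitor, glycolysis and peritubular in the interaction, progenitor and spermatid under vehicle, oxidative phosphorylation for inhibitor in wild type, and stem cell for inhibitor in the knockout. Lists called for knockout against wild type under inhibitor numbered 8 with the peritubular term and 14 without the 2 libraries farthest apart. For inhibitor-treated knockout against vehicle-treated wild type they numbered 3 with the peritubular term, 3 with both content terms, 3 with library-number set added, and 2 without the 2 libraries. With each library left out the counts ran from 3 (without KO_PD replicate 3) to 14 (without WT_PD replicate 3) for knockout against wild type under inhibitor, 6 (without WT_vehicle replicate 4) to 11 (without WT_PD replicate 3) for inhibitor in wild type, 6 (without KO_PD replicate 3) to 14 (without KO_vehicle replicate 4 or KO_PD replicate 2) for inhibitor in the knockout, 6 (without KO_PD replicate 2) to 13 (without KO_vehicle replicate 4) for the interaction, and 1 to 6 (without KO_PD replicate 4) for inhibitor-treated knockout against vehicle-treated wild type. In the last the count was 1 only without WT_vehicle replicate 2 or 3, and 2 to 4 without any other library except KO_PD replicate 4. In the first it was also 8 without KO_PD replicate 4.

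The oxidative phosphorylation interaction reversed to -0.049 with the peritubular term and -0.062 with both terms. For inhibitor in wild type, the mitotic list reversed to 0.038 and DNA replication to 0.029 without the 2 libraries, and likewise without WT_PD replicate 3, and the mitotic list to 0.017 without WT_vehicle replicate 4. With each library left out they ran from -0.097 to 0.038 and from -0.098 to 0.029. DNA replication for knockout against wild type under inhibitor reversed to -0.018 without the 2 libraries and without WT_PD replicate 3, and reached 0.11 without WT_PD replicate 2.

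Spry4 under vehicle was -1.01 with the replicate number as a block (exact sign-flip permutation p = 0.125, the smallest possible), and -1.16 to -0.84 with each library left out. The exact permutation p was 0.0571 without WT_vehicle replicate 1, 2 or 3 (-0.997, -0.97 and -1.01). Replicate numbers did not pair the libraries: 10 of 24 same-number pairs correlated above 0.1. Under inhibitor Spry4 was -0.96 to -0.57, the first without KO_PD replicate 4, the library that overlapped wild type (exact permutation p = 0.0286). Across genes, r of the inhibitor effects in the genotypes ran from -0.50 to 0.17 and r of the knockout effects from -0.33 to 0.32, each highest without WT_PD replicate 2.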

Other observations

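The fit with 3 terms and its variants were chosen after the data were seen.

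When the peritubular and spermatid list means and the library-number set were terms in limma, 783 genes differed between knockout and wild type under inhibitor, 558 of them lower in the knockout and the others higher, with 3461 at an unadjusted p under 0.05. Higher genes included Foxo6 (log2 difference 0.70, SE 0.09), the immediate early gene Arc (0.55, SE 0.09), the transcription factor gene Nfatc2 (0.53, SE 0.08) and Phgdh (0.48, SE 0.08). Lower genes included Dynlt3 (-0.88, SE 0.09), the syndecan gene Sdc2 (-0.76, SE 0.11) and Spry4 (-0.93, SE 0.16, adjusted p = 0.0157). Of the DNA replication list 5 of 18 members were higher (Mcm2, Mcm3, Mcm5, Cdt1 and E2f1) and 0 lower, and of the apoptosis regulators Bcl2 and Xiap were lower. In other lists the members past the threshold were higher: Ccnb2 and Ube2c (mitotic), Phgdh and Slc7a5 (ATF4 targets), Egr2 (immediate early and GDNF-responsive), Tspan8 (stem cell and GDNF-responsive), Sall4 (pan-undifferentiated) and Cd68 (macrophage), while mt-Nd5 was lower. Directions differed for ERK outputs, with Etv4 higher and Etv1 lower, and of 15 quiescence and FOXO targets Cdkn1c was higher while Cdkn1b, Trp53inp2 and Rbl2 were lower. These genes were chosen after their values were seen.

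Of the 35 splits of these libraries 1 gave as many genes, the real one, and the highest other gave 1. This held for the fit taken alone and for the most genes over the 5 fits with terms. A share of 1 in 35 is the lowest that these splits allow. It cannot exclude chance here, because the fit was chosen after its count was seen. The splits were also not limited to those balanced over the library numbers, as the real grouping is. The library-number set is a term in the fit, so unbalanced splits share variance with that term and the real grouping does not. With the most genes over 7 fits, those without terms included, 2 of 35 splits were as large (highest other 3066), and with library weights as an 8th fit 18 of 35 (highest other 5499, weights not converged in some splits). The number of splits as large thus rests on which fits are counted, and whether chance is excluded is left open here. The count rested on single libraries: it was 0 without WT_PD replicate 3, 193 without KO_PD replicate 2, 204 without KO_PD replicate 4 and 927 without KO_vehicle replicate 3. With the peritubular term and library-number set alone it was 240, and with the spermatid term and that set 0. A genotype effect under inhibitor that content differences hide may account for the 783 genes, and so could the terms' fit to WT_PD replicate 3, the library with the most Acta2.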
